A study of Mus musculus with 2 samples.

How the data were processed

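The series measured gene expression in single cells of the mouse spinal cord around an experimental injury. Adult NG2-eGFP mice, 12 to 14 weeks old, received vehicle or the growth factor PDGF-BB after spinal cord injury. Their cords were taken 3, 7 and 14 days after the administration, which are 10, 14 and 21 days after injury. Cords of uninjured mice served as naive controls. Per the labels' protocols, about 2 mm of cord around the lesion was collected, and 3 cords (naive, day 3 and day 7) or 2 cords (day 14) were combined into each pool. The tissue was fixed, stored frozen, dissociated with an enzyme and hybridised with the barcoded probes of the 10x Genomics Flex assay, to which probes for eGFP had been added. The assay reads probes and not transcripts, so a level depends on how well a gene's probes bind.

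There were 2 samples, each a capture well holding 4 pools told apart by their probe barcode. One well held uninjured pool 1 and the 3 vehicle pools, and the other held uninjured pool 2 and the 3 PDGF-BB pools. Treatment and capture well were therefore the same split of the injured pools. Which matrix belonged to which pool was read from the matrices' own names against the days in the labels, and the probe barcode of every cell matched its pool. A pool was the unit of replication, with 1 pool per treatment and day. Each pool mixes animals, so p-values measure the spread between pools.

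The deposited matrices held whole-number UMI counts per gene and cell, made with Cell Ranger 8.0.1 per the file headers and on the mm10 genome per the submitters' processing notes. The counts were not normalized. They covered 19066 genes, of which 18963 matched a protein-coding gene of the mm10 annotation used here for positions. The cell caller's settings are not given in the sources used here. The matrices held 38169 cells.

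Cells with at least 500 UMIs, at least 300 genes and at most 10% mitochondrial UMIs passed, which left 37846 cells. Doublet scores came from the scrublet method in scanpy 1.11.5. Its automatic threshold marked 241 cells, 0.637% of them and under 0.5% in 6 pools, so it was not used. Instead the highest scores of each pool were removed at a rate of 0.8% per 1000 cells, which took 1606 cells (4.24%) and left 36240. Cells were clustered on 2000 variable genes, 30 principal components and 15 neighbours with the Leiden method at resolution 1 (igraph 0.11.9), which gave 35 clusters. Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.

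A cluster was named from markers of 18 cell types when at least 3 markers of a type were raised at least 2-fold (pseudocount 5 CPM), and stayed unnamed when its 10 leading genes went against the name, when over 50% of its cells scored as doublets, or when over 75% came from 1 pool. The markers were fixed before the data were examined, but this rule and the set of cells it used as a reference were settled after the clusters had been seen, and several references were tried. Under the rule 27 clusters were named. The choice of reference decided whether the pericyte cluster (29, led by Higd1b, Abcc9, Notch3 and Kcnj8) and the neuron clusters 11, 14 and 24 had a name. The rule for leading genes left out cluster 6 (oligodendrocyte genes such as Hapln2, Tmprss5 and Carns1), cluster 10 (myeloid genes such as Capn3, Abi3, Rgs1 and Ccl3), cluster 32 (C1qa, C1qb and Apoc1) and cluster 4, where all 8 oligodendrocyte markers were raised but Slc18a3, Calca and Slc5a7 led. Cluster 30, led by Chat, met no marker set, cluster 13 came mostly from 1 pool (80%), and clusters 15 and 20 were mostly doublets (77.3% and 76.7%). The unnamed clusters held 11.8% and 12.1% of the cells of uninjured pools 1 and 2. They held 20.2%, 22.2% and 18.4% of the cells of the vehicle pools at days 3, 7 and 14, and 22.6%, 18.8% and 15.0% of those of the PDGF-BB pools. All names below stand for cells that are like the type. The class called macrophage joins cluster 19 (Gpnmb, Lyz2 and Hpse) and cluster 25 (Mrc1, Cd163, F13a1 and Lyve1). The class called microglia is cluster 22 alone. Clusters 10 and 32 also scored highest for the microglia markers, with 7 of 7 and 6 of 7 raised, but stayed unnamed. At Leiden resolution 2 the rule named microglia a cluster led by Rgs1 and Ccl3 (1436 cells), which are also among the leading genes of cluster 10. It also named so a cluster led by C1qa and Spp1 (680 cells), while other clusters that scored highest as microglia stayed unnamed.

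Raw counts were summed per pool and class. The 8 planned classes each had at least 20 cells in every pool. The sums were tested with edgeR 4.0.16 in R 4.3.3, with its low-count filter, TMM scaling and the quasi-likelihood test, and p-values were adjusted by the Benjamini-Hochberg method within a class, with a threshold of 0.05. The 3 comparisons were PDGF-BB against vehicle over the 6 injured pools with day as a covariate, the 3 vehicle pools against the 2 uninjured pools, and day 14 against day 3 with treatment as a covariate. Shares of cells were compared by an exact two-sided sign-flip permutation of the log2 ratio over the 3 days, whose smallest p is 0.25. The 24 gene lists fixed beforehand were tested with camera (limma 3.58.1) at its preset correlation of 0.01 wherever at least 5 members were measured, with adjustment over lists and classes. Calls of single members were also adjusted over the list alone. Gene levels are CPM, a gene's counts relative to the total UMIs of a class. Those given for single genes in the comparisons use the TMM-scaled library sizes of the fit, and those given as raw CPM use the class sum. Intervals have a level of 0.95, are exact (Poisson for counts, binomial for shares) and cover counting error only. The limit given for a share of 0 is 3 counts of the total. A fold against a group of pools without a UMI was computed against a floor of 3 counts over the group.

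The groups, tests, gene lists, cell type markers, named genes and most alternative settings were chosen before the data were examined. The genes named for a class and comparison were the 5 with the highest and the 5 with the lowest log2 fold change among those past the threshold, with a mean of at least 20 CPM and the same direction at every day (or, against naive cord, with both uninjured pools on 1 side of all vehicle pools). To these came up to 4 called members of each list past the threshold and 21 fixed genes. The text gives about 20 to 30 of them per comparison, from the pericyte, fibroblast, endothelial and astrocyte classes first. Genes outside this rule are said to be so where they stand, and some genes within it are not reported here. Tests of neurons, committed oligodendrocytes and clusters 6 and 10, lists of corticosteroid-responsive, clock and Y-linked genes, the runs without single pools in the time comparison and the runs of shares and lists without a day or pool were added after seeing the data.

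The test was tried on simulated data, with counts drawn for the real genes at the real means and depths of a class and a seeded set of genes changed. Each gene had 1 mean over the pools and a spread read from the trend over genes. The simulated pools thus had no difference of day, capture well or animals, and the shares of false calls hold for that setting only. For PDGF-BB against vehicle in pericytes, edgeR recovered 57.7% of the genes changed by a log2 fold of 1 and 94.9% of those changed by 2, and 6.88% of its calls were false. In astrocytes it recovered 68.7% and 96.0%, with 2.98% false. Against naive cord, 38% and 95.7% were recovered in pericytes (3.05% false) and 82.1% and 96.0% in astrocytes (1.14% false). For day 14 against day 3 these were 20.6% and 81.4% in pericytes (5.71% false) and 65.7% and 90.9% in astrocytes (3.73% false).

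The alternatives were DESeq2 1.42.0, RLE scaling, no low-count filter, doublets kept, at least 1000 UMIs per cell, no day term, the uninjured pools as an offset of the capture well, all 8 pools in 1 fit, each day or pool left out, Leiden resolution 2, cells thinned to 1000 UMIs, and camera with an estimated correlation or fry for the lists. Total UMIs per pool ran from 12369974 to 70199890 and the median UMIs per cell from 2716.5 to 6679, so the day 3 pools carry the least precise values. Sequencing reads were not used here.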

Results

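Single-cell gene expression was measured at the site of a spinal cord injury in adult NG2-eGFP mice, in which eGFP is driven by sequence of Cspg4, the gene of the proteoglycan NG2 made by pericytes and oligodendrocyte progenitors. Pericytes wrap the capillaries and carry PDGFRB, a receptor of PDGF-BB. The title of the series concerns programming pericytes in the living animal so that they bridge the lesion and help axons regrow. The 8 pools were 2 of uninjured cord, 3 of vehicle and 3 of PDGF-BB, the last 6 taken 3, 7 and 14 days after the administration. The files held 47159796 and 54362150 UMIs for uninjured pools 1 and 2. The vehicle pools held 14488349, 52589320 and 53512388 UMIs at days 3, 7 and 14, and the PDGF-BB pools 12369974, 31153423 and 70199890. After filtering, the uninjured pools kept 3689 and 4004 cells, the vehicle pools 2648, 6540 and 5789, and the PDGF-BB pools 2869, 4193 and 6508. The median cell of the day 3 pools held 3059 (vehicle) and 2716.5 (PDGF-BB) UMIs, and that of the other pools between 4175 and 6679.

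Named clusters included neurons, oligodendrocytes and their progenitors (OPCs), astrocytes, fibroblasts, endothelial cells, microglia, macrophages and a small cluster of pericytes. The pericyte class had 36 and 42 cells in the uninjured pools, 35, 61 and 55 in the vehicle pools at days 3, 7 and 14, and 25, 51 and 62 in the PDGF-BB pools. Macrophages made up 0.57% and 0.55% of the cells of uninjured cord and between 3.37% and 10.4% of those of injured cord. In uninjured cord they were nearly all of cluster 25, with genes of border macrophages, and in injured cord mostly of cluster 19, with genes of lipid-laden phagocytes. Cluster 10, unnamed and led by myeloid genes, made up 0.35% and 0.20% of the uninjured pools, 10.5%, 10.4% and 7.98% of the vehicle pools at days 3, 7 and 14, and 14.4%, 8.51% and 4.93% of the PDGF-BB pools. The pools were not sorted, so these shares also depend on how well each cell type survived dissociation.

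The pools were compared for the genes that mark their animals, which was decided after the values were seen. The vehicle day 7 pool held almost no transcripts of the 4 Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d (0.0819 raw CPM, against 150.3 to 267.9 in the other 7 pools). A Y-linked UMI was seen in 0 of its 441 cells with at least 20000 UMIs, which allows a share of up to 0.68%, whereas 29.8% to 56.4% of such cells in the other pools had none. The median Y-linked UMIs of such cells were 0 in vehicle day 3 and 6 in PDGF-BB day 3, where 56.4% and 35.3% had none. They were 3 in vehicle day 14, 7 in PDGF-BB day 7, 4 in PDGF-BB day 14 and 1 in each uninjured pool. Whether these pools mixed animals with and without Y-linked transcripts was not tested. The transgene was close to absent in the vehicle day 14 pool, with 1 eGFP UMI (0.0202 CPM) against 9.37 to 27.5 CPM elsewhere. In that pool 5 of the 10669 genes with at least 20 CPM lay more than 2-fold below every other pool, namely eGFP, Cimap1c, Imp3, Snupn and Snx33. The last 4 lie within 100 kb of Cspg4 (chromosome 9, 56865033 to 56899870 in mm10). In neurons Cspg4 itself was at 1.53 CPM in this pool and at 26.7 to 58.5 CPM in the other pools. Every comparison below that uses vehicle day 7 or vehicle day 14 therefore also compares animals that differ in Y-linked transcripts or in transcripts of this region. The day 3 pools may differ in Y-linked transcripts as well, by the medians above.

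**Figure D1:**
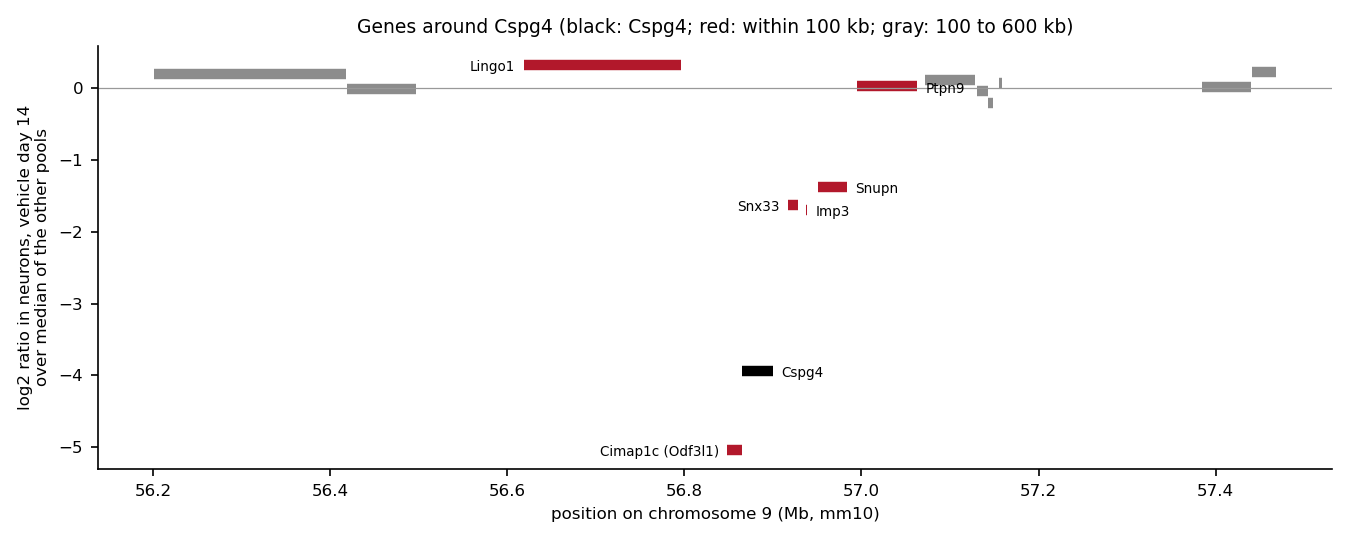
Log2 ratio of vehicle day 14 to the median of the other pools in neurons, for genes along chromosome 9 (position in Mb, mm10) around Cspg4. Cimap1c (-5.04), Cspg4 (-3.94), Imp3 (-1.70), Snx33 (-1.63) and Snupn (-1.38) lie low, and Lingo1 (0.33) and Ptpn9 (0.03) on either side do not.

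eGFP was highest in the classes that make NG2. Over all pools OPCs had 99.2 CPM (95% interval 90.0 to 109) and pericytes 59.9 CPM (52.9 to 67.7), against 15.4 CPM in neurons, 5.20 CPM in fibroblasts and 1.82 CPM (0.668 to 3.96) in microglia. Microglia were the lowest of the classes measured. Among other myeloid cells, cluster 10 had 14.2 CPM (11.4 to 17.6) and macrophages 11.6 CPM (9.57 to 13.9), close to neurons. An eGFP UMI was seen in 26.7% of OPCs, 28.1% of pericytes, 16.2% of neurons and 0.532% of microglia, a type that should lack the gene. With every cell thinned to 1000 UMIs, these shares were 9.88%, 5.92%, 1.32% and 0.091%. The thinning left out 46 OPCs, 12 pericytes, 402 neurons and 30 microglia.

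The question of the study was what PDGF-BB does to pericytes and their neighbours after injury. In the pericyte class 3 genes rose after PDGF-BB and 2 fell, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Tagln (ENSMUSG00000032085, chromosome 9, 45929619 to 45936058), which encodes the actin-binding protein transgelin of contractile cells, had 289, 91.3 and 186 CPM at days 3, 7 and 14 after PDGF-BB against 66.1, 16.1 and 37.3 CPM after vehicle (log2 fold change 2.29 ± 0.22 SE, adjusted p = 0.00106). Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042), a chain of type I collagen, had 1504, 88.4 and 134 CPM against 412, 35.2 and 37.3 CPM (1.73 ± 0.20, adjusted p = 0.00295). Tpm2 (ENSMUSG00000028464, chromosome 4, 43514711 to 43523765), a tropomyosin, had a log2 fold change of 1.23 ± 0.19 (adjusted p = 0.0313). Cebpd, a transcription factor induced by inflammation and glucocorticoids, fell by 1.18 ± 0.17 on the log2 scale (adjusted p = 0.026), and Depp1, a FOXO target, fell by 1.42 ± 0.22 (adjusted p = 0.0313).

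Genes that define pericytes did not pass the test. Pdgfrb, a receptor of PDGF-BB, had a log2 fold change of -0.02 ± 0.20, Cspg4 of 0.07, the potassium channel subunit Kcnj8 of -0.57 and the G-protein regulator Rgs5 of -0.15. Acta2, smooth muscle actin, had 1.89 ± 0.32 (adjusted p = 0.0697) and eGFP 2.83 ± 0.51 (adjusted p = 0.0947). Among the fixed lists, 9 of 9 contractile genes were higher, 2 of them past the threshold over all genes and 5 adjusted over the list alone (median log2 fold change 0.85, camera adjusted p = 4.32e-20, adjusted p = 0.603 with an estimated correlation). Fibrillar matrix genes were higher in 10 of 14, with 1 called over all genes and 1 adjusted over the list alone (adjusted p = 6.85e-04, adjusted p = 0.603 with an estimated correlation). Genes of the early response to growth factors were higher in 1 of 11, with 0 called by edgeR over all genes or over the list alone (adjusted p = 0.0018, adjusted p = 0.603 with an estimated correlation). Pericyte identity genes were higher in 3 of 11, again with 0 called (adjusted p = 0.0428, adjusted p = 0.801 with an estimated correlation).

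Markers of other cell types moved with these genes in the pericyte class. The smooth muscle markers were higher in 5 of 5 (median 1.35) the fibroblast markers in 7 of 8 (median 0.61) and the OPC markers in 5 of 5 (median 0.64). Oligodendrocyte markers were lower in 8 of 8 (median -0.12), endothelial markers in 7 of 7 (median -0.10) and astrocyte markers in 6 of 8 (median -0.35). Few cells carried Tagln. In PDGF-BB day 3 the class had 51 Tagln UMIs in 2 of 25 cells, with 92.2% in 1 cell, and in vehicle day 3 it had 17 UMIs in 3 of 35 cells, with 88.2% in 1 cell. In PDGF-BB days 7 and 14, 10 of 51 and 9 of 62 cells had a Tagln UMI. Without day 3 the log2 fold change of Tagln was 2.37 and still past the threshold, while Tpm2 had 1.06 without day 3 and 1.25 without day 7 and did not pass. Depp1 did not pass without day 7 (-1.54) or day 14 (-1.07), nor did Cebpd without day 7 (-1.09). With the uninjured pools as an offset of the capture well, Tagln (2.46) and Col1a1 (7.07) passed, and Tpm2, Cebpd and Depp1 did not. The Col1a1 value rests on uninjured pools that differ, with 293 UMIs in 7 cells of pool 1 and 6 UMIs in 3 cells of pool 2. Most of the UMIs in uninjured pool 1 were held by 2 cells, so the offset of Col1a1 depends on few cells.

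In the fibroblast class genes of phagocytes fell after PDGF-BB, as did the matrix genes Fn1 and Ccn2. Ptgds (ENSMUSG00000015090, chromosome 2, 25466709 to 25470046), the prostaglandin D2 synthase of meningeal cells, had 1973, 3823 and 7826 CPM at days 3, 7 and 14 after PDGF-BB against 15580, 15423 and 28052 CPM after vehicle (log2 fold change -2.27 ± 0.24, adjusted p = 0.00175 by edgeR's quasi-likelihood test). Cd300a, an inhibitory receptor of myeloid cells, fell by 2.31 ± 0.26 on the log2 scale (adjusted p = 0.00205), and Fcgr2b, an inhibitory Fc receptor, by 2.03 ± 0.28 (adjusted p = 0.0053). Gpnmb (ENSMUSG00000029816, chromosome 6, 49036546 to 49070929), a glycoprotein of lipid-laden phagocytes, fell by 2.02 ± 0.34 (adjusted p = 0.0116), but turned to 0.98 with the uninjured pools as an offset of the capture well. With that offset edgeR called 0 genes in fibroblasts (621 at an unadjusted p under 0.05), so the other genes named here lost their calls as well. Plin4, which coats lipid droplets and is also the leading gene of oligodendrocyte cluster 2, fell by 1.87 ± 0.21 (adjusted p = 0.00175). Fn1, which encodes fibronectin, fell by 0.86 ± 0.17 (adjusted p = 0.032), and Ccn2, a matrix protein induced by TGF-beta, by 0.86 ± 0.16 (adjusted p = 0.021). Neither passed without day 3 (Fn1 -0.88, Ccn2 -0.86) or without day 7 (Fn1 -0.72, Ccn2 -0.82). Higher after PDGF-BB were Shank3, a scaffold of excitatory synapses (1.16 ± 0.15, adjusted p = 0.00342), Coro6 (1.04, adjusted p = 0.00867) and Snhg11, a noncoding RNA (0.95, adjusted p = 0.0179, and not past the threshold without day 3, at 0.79). Coro6 and Snhg11 are also among the leading genes of neuron clusters 1 and 12. The other 2 higher genes, Snupn (1.63) and Imp3 (0.89), lie next to Cspg4 and are among those that were low in vehicle day 14. Imp3 did not pass without day 3, 7 or 14 (1.05, 0.88 and 0.65), nor Snupn without day 3 (1.70). Col1a1 (-0.10), Col4a1 (0.41) and Lama4 (-0.36) did not pass.

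In fibroblasts the list of lipid-laden phagocyte genes was lower in 13 of 13 members, 4 of them called and 9 adjusted over the list alone (camera adjusted p = 3.37e-12, adjusted p = 0.603 with an estimated correlation). Its called members included Apoe (-1.30 ± 0.19, adjusted p = 0.00762) and the lipid receptor Trem2 (-1.07, adjusted p = 0.0394). Apoe did not pass without day 3 (-1.30) or day 7 (-1.35), nor Trem2 without day 7 (-0.99) or day 14 (-0.71). Complement and MHC genes were lower in 11 of 11, with 0 called by edgeR over all genes and 6 adjusted over the list alone (adjusted p = 2.82e-05, adjusted p = 0.644 with an estimated correlation). TGF-beta targets were higher in 1 of 9, with 2 called lower and 5 adjusted over the list alone (adjusted p = 5.6e-04, adjusted p = 0.603 with an estimated correlation). Genes of the fibrillar matrix were higher in 4 of 19, with 1 called lower and 5 adjusted over the list alone (adjusted p = 4.73e-04, adjusted p = 0.755 with an estimated correlation). Homeostatic microglia genes, which fibroblasts should lack, were higher in 2 of 7, with 2 called lower (adjusted p = 0.00222, adjusted p = 0.603 with an estimated correlation). Markers of macrophages moved the same way in this class, with 2 of 6 higher, 2 called lower and a median of -0.74. Oligodendrocyte markers were lower in 8 of 8 (median -0.34), and neuron markers were higher in 6 of 9 (median 0.49).

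**Figure D2:**
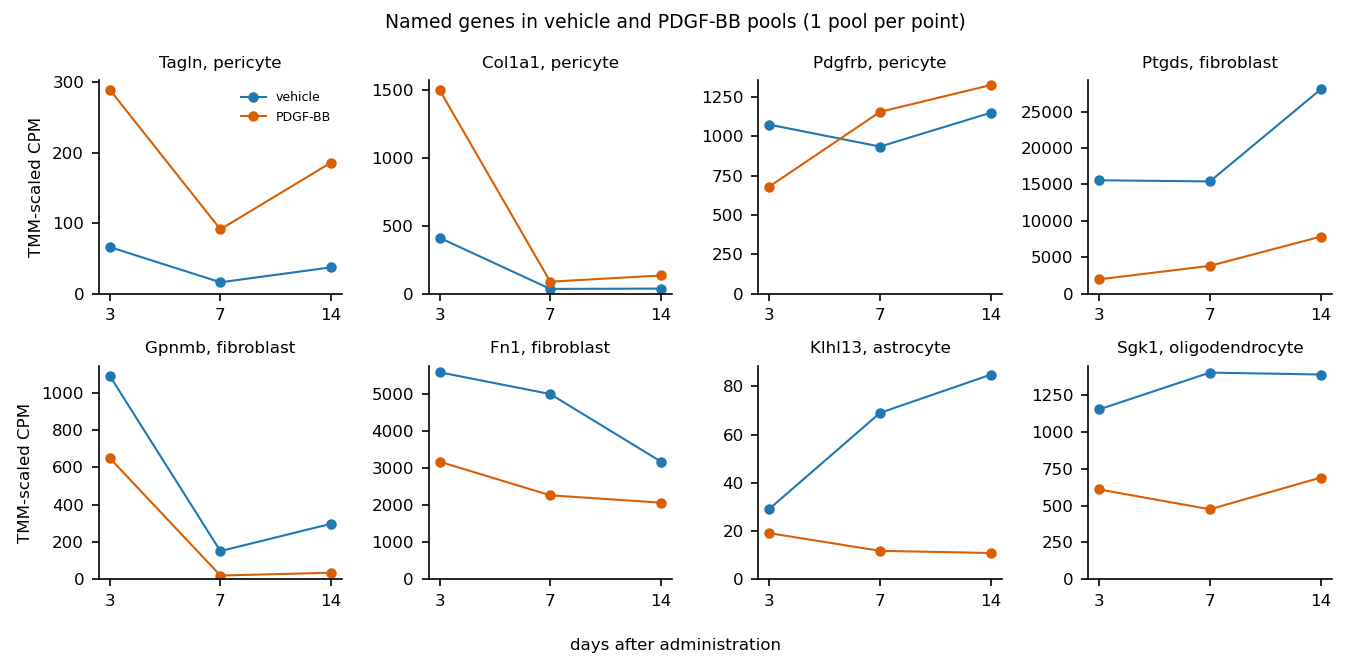
TMM-scaled CPM against days after administration in the vehicle and PDGF-BB pools, 1 pool per point, for genes of the pericyte, fibroblast, astrocyte and oligodendrocyte classes. Tagln in pericytes is higher after PDGF-BB at each day (289 against 66.1 CPM at day 3), and Ptgds in fibroblasts is lower (1973 against 15580 CPM at day 3).

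In astrocytes 4 genes fell after PDGF-BB, the matrix genes Ccn5 and Col6a2 among them, and no reactive astrocyte gene passed the test over all genes. Klhl13 (ENSMUSG00000036782, chromosome X, 23219271 to 23365082), an adaptor of a ubiquitin ligase, fell by 2.41 ± 0.29 on the log2 scale (adjusted p = 0.0182 by edgeR's quasi-likelihood test). The matricellular gene Ccn5 fell by 1.35 ± 0.19 (adjusted p = 0.0426) and the collagen chain Col6a2 by 0.93 ± 0.13 (adjusted p = 0.0426). Reactive astrocyte genes were lower in 12 of 12, with 0 called by edgeR over all genes and 8 adjusted over the list alone (camera adjusted p = 1.5e-12, adjusted p = 0.603 with an estimated correlation). Among them the intermediate filament genes Gfap and Vim had -0.40 and -0.96 (adjusted p = 0.744 and 0.235). Genes of the fibrillar matrix were higher in 2 of 19, with 1 called lower and 11 adjusted over the list alone (adjusted p = 5.61e-16, adjusted p = 0.603 with an estimated correlation). For the TGF-beta targets the test read lower (adjusted p = 0.0415, adjusted p = 0.603 with an estimated correlation) with a mean of -0.38 and a median of 0.02. In this class fibroblast markers were lower in 9 of 10 (median -0.18) and neuron markers higher in 8 of 9 (median 0.31). Without day 14, 235 genes were called higher and 578 lower in this class, and with the uninjured pools as an offset edgeR called 0 (350 at an unadjusted p under 0.05).

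Endothelial cells had 4 lower genes after PDGF-BB by edgeR's quasi-likelihood test. Alas2, the heme synthesis gene of red cell precursors, fell by 3.92 ± 0.62 (adjusted p = 0.0387), Depp1 by 1.48 ± 0.21 and the lipocalin Apod by 1.38 ± 0.19 (both adjusted p = 0.0192). The last, Plin4 (-1.95 ± 0.32, adjusted p = 0.0393), was not of the same direction at every day and is named after its value was seen. Plin4 is also the leading gene of oligodendrocyte cluster 2. Without day 14, Alas2 (-1.80), Depp1 (-1.16) and Apod (-1.27) did not pass. With the uninjured pools as an offset, Depp1 and Apod did not pass, while Alas2 had -5.25 and Plin4 -5.01. Oligodendrocyte markers were lower in 8 of 8 in this class (median -0.39) and pericyte markers in 5 of 5 (median -0.13), and astrocyte markers were higher in 7 of 7 (median 0.26). The lipid-laden phagocyte genes were higher in 2 of 10, with 3 lower adjusted over the list alone (camera adjusted p = 0.00268, adjusted p = 0.603 with an estimated correlation). In macrophages Cbr2, a carbonyl reductase (1.61, adjusted p = 0.00553), and Cd5l, a secreted protein of macrophages (1.57, adjusted p = 0.0141), rose. The class joins cluster 25, which has Cbr2 among its leading genes and whose share had log2 ratios of 0.69, 1.40 and 0.27 at days 3, 7 and 14, and cluster 19, with 0.63, -0.63 and -0.58. Macrophage markers were higher in 7 of 9 in the class (median 0.52), while astrocyte markers were lower in 7 of 8 (median -0.55), fibroblast markers in 7 of 8 (median -0.32) and OPC markers in 6 of 7 (median -0.43). Mt2, a metallothionein (-0.88, adjusted p = 0.00553), the clock gene Per1 (-0.78, adjusted p = 0.0141) and Col6a3 (-0.77, adjusted p = 0.0141) fell. Best1, named after its value was seen, had -2.05 ± 0.36 (adjusted p = 0.044), but 4.39 with the uninjured pools as an offset of the capture well, under which the other macrophage genes named here did not pass. Without day 7, Cd5l (0.71) did not pass. In microglia Ptgds was the gene called (-1.07, adjusted p = 0.0386), and it did not pass without day 7 (-1.12) or with that offset.

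Oligodendrocytes had 15 higher and 36 lower genes. Sgk1 (ENSMUSG00000019970, chromosome 10, 21882184 to 21999903), a kinase induced by glucocorticoids, had 609, 475 and 688 CPM at days 3, 7 and 14 after PDGF-BB against 1151, 1399 and 1386 CPM after vehicle (log2 fold change -1.17 ± 0.11, adjusted p = 5.31e-05 by edgeR's quasi-likelihood test). Plin4 fell by 1.02 ± 0.08 (adjusted p = 2.55e-05) and Pdk4, a kinase that restrains glucose oxidation, by 1.52 (adjusted p = 4.78e-04). Higher were Arc, an early gene of neuronal activity (0.70, adjusted p = 0.0262), the stress gene Atf3 (1.94, adjusted p = 0.0244), Nuak1 (0.50, adjusted p = 0.0141), Imp3 (0.98, adjusted p = 0.0329) and eGFP (2.82, adjusted p = 0.0205). Without day 7, Arc (0.54) and Atf3 (0.65) did not pass, nor did Nuak1 (0.51), Imp3 (0.50) and eGFP (2.04) without day 14, the day of the vehicle pool that lacks eGFP. With the uninjured pools as an offset, Plin4 and Pdk4 passed and the other genes named here did not. Astrocyte markers were lower in 8 of 8 in this class (1 called, median -0.17) and fibroblast markers in 6 of 8 (1 called, median -0.26). Interferon response genes were higher in 7 of 9 (camera adjusted p = 0.009997, adjusted p = 0.603 with an estimated correlation), with 0 called by edgeR over all genes and 1 adjusted over the list alone. Cholesterol synthesis genes were higher in 9 of 12, with 0 called over all genes and 1 adjusted over the list alone (adjusted p = 0.0167, adjusted p = 0.801 with an estimated correlation).

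A list of 18 genes known to be induced by corticosteroids, drawn up after Sgk1, Plin4 and Per1 had been seen, was lower after PDGF-BB in most classes. It was lower in 17 of 17 measured members in fibroblasts (7 called lower, median -0.63), 16 of 16 in oligodendrocytes (9 called lower, median -0.62), 16 of 17 in pericytes (1 called lower, median -0.41) and 15 of 15 in astrocytes (median -0.37). In astrocytes 0 of them were called by edgeR. It was lower in 12 of 14 in endothelial cells, 9 of 11 in microglia, 10 of 11 in macrophages and 11 of 13 in OPCs. The list was not fixed beforehand, so these counts describe it and do not test it. Among all genes called, 4.46% were higher in fibroblasts and 29.4% in oligodendrocytes. At day 3 alone the median of the list was above 0 in endothelial cells (0.37), macrophages (0.10) and OPCs (0.18). Per1, itself a clock gene, was counted in this list. Of 11 other clock genes, 0 were called by edgeR in any class, with medians between 0.04 and 0.25.

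In the order pericyte, fibroblast, endothelial, astrocyte, microglia, macrophage, OPC and oligodendrocyte, edgeR tested 9421, 11985, 7996, 12575, 7817, 10319, 10046 and 11479 genes. It called 5, 112, 4, 4, 1, 7, 0 and 51 of them between PDGF-BB and vehicle. At an unadjusted p under 0.05 there were 520, 1545, 402, 914, 342, 814, 413 and 1002 genes. DESeq2 called 5, 54, 3, 9, 0, 0, 1 and 16. Without day 3 edgeR called 6, 43, 46, 9, 1, 74, 31 and 313 genes, without day 7 it called 8, 68, 39, 13, 0, 40, 0 and 54, and without day 14 it called 19, 214, 2, 813, 39, 97, 5 and 21. Without the day term it called 0 in each of the 8 classes, with 332, 921, 278, 484, 216, 338, 240 and 322 genes at an unadjusted p under 0.05. With the uninjured pools as an offset of the capture well it called 20, 0, 12, 0, 0, 2, 0 and 4. Since each treatment was a single capture well, the offset of the wells and PDGF-BB cannot be told apart except through the uninjured pools.

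Shares of the cell classes were compared between PDGF-BB and vehicle, where the exact sign-flip permutation test over 3 days cannot reach a p under 0.25. Pericytes were 0.87%, 1.22% and 0.95% of cells at days 3, 7 and 14 after PDGF-BB and 1.32%, 0.93% and 0.95% after vehicle (mean log2 ratio -0.07, exact permutation p = 1). The ratio was in the same direction at all 3 days for OPCs (mean log2 ratio -0.23, exact permutation p = 0.25), endothelial cells (0.16, exact permutation p = 0.25), ependymal cells (0.43, exact permutation p = 0.25) and cluster 25, the border macrophages (0.79, exact permutation p = 0.25). The ratio of ependymal cells between the uninjured pools of the wells was as large (0.43), and that of cluster 25 was 0.02. At Leiden resolution 2 the ratio of OPCs was 0.0296 at day 3, and endothelial cells had 0.24, -0.0874 and -0.0221 at days 3, 7 and 14 (mean 0.0437, exact permutation p = 1). Fibroblasts had log2 ratios of 0.59, 0.19 and -0.21, and macrophages of 0.63, -0.30 and -0.36, at days 3, 7 and 14.

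**Figure D3:**
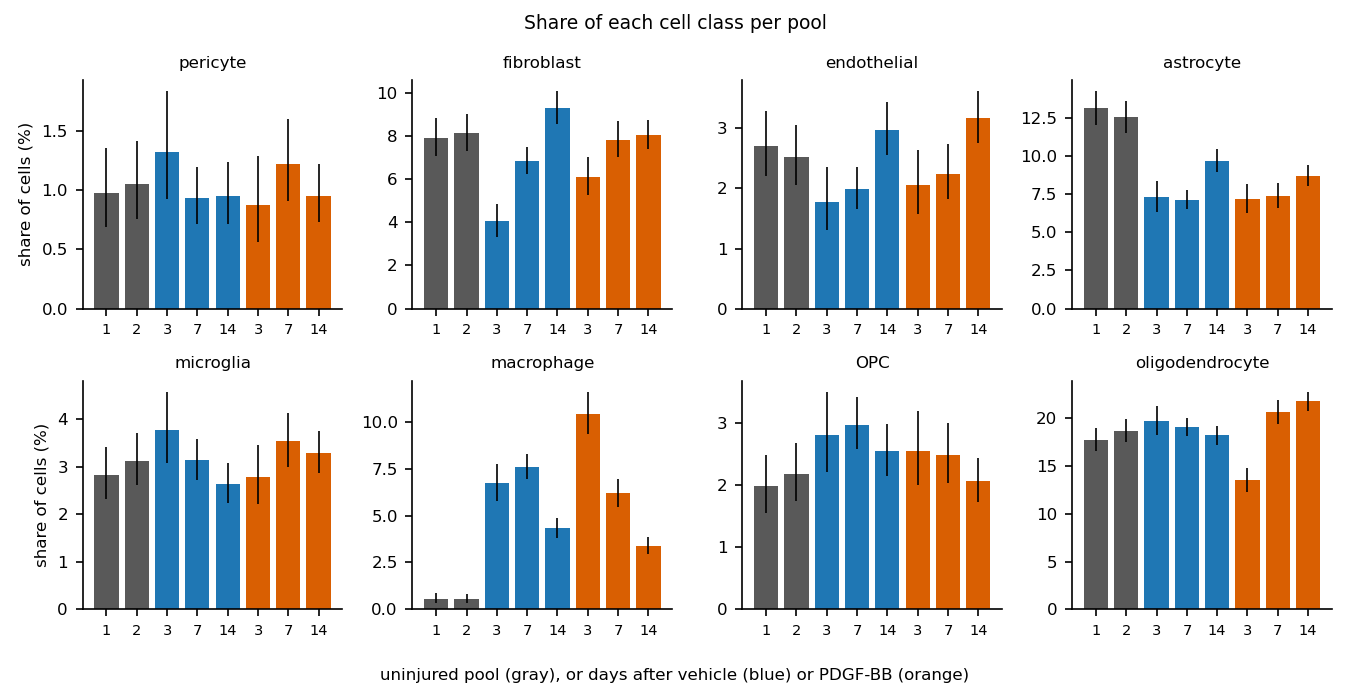
Percent of cells in each of 8 classes per pool (bars, with exact 95% binomial intervals), with uninjured pools in gray, vehicle in blue and PDGF-BB in orange. Pericytes lie between 0.87% and 1.32% in all pools, and macrophages between 3.37% and 10.4% in injured against 0.55% and 0.57% in uninjured pools.

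Injury without PDGF-BB was read from the vehicle pools against uninjured cord. These groups also differed in the median mitochondrial share of UMIs per cell. It was 0.66% and 0.71% in the uninjured pools and 0.13%, 0.23% and 0.17% in the vehicle pools at days 3, 7 and 14. In astrocytes genes of the reactive state and of the fibrillar matrix rose. Gfap (ENSMUSG00000020932, chromosome 11, 102887336 to 102900912) rose by 2.06 ± 0.24 on the log2 scale (adjusted p = 4.72e-04 by edgeR's quasi-likelihood test), Vim by 3.98 ± 0.50 (adjusted p = 6.48e-04) and Fn1 by 4.18 (adjusted p = 0.00513). Ccn5 rose by 8.12 ± 0.70 (adjusted p = 1.67e-04), Ptx3, a secreted pentraxin, by 6.85 (adjusted p = 1.41e-04), the protease inhibitor Timp1 by 6.34 (adjusted p = 3.64e-04), the iron-binding Lcn2 by 4.95 (adjusted p = 2.17e-04) and the matrix glycoprotein Tnc by 2.23 (adjusted p = 0.00118). Igfbpl1 was 178-fold higher (counting interval 60.8 to 867) and the transglutaminase Tgm1 120-fold (40.7 to 582), each against 3 UMIs in uninjured astrocytes. Reactive astrocyte genes were higher in 12 of 12, with all 12 called (camera adjusted p = 1.97e-18, adjusted p = 0.292 with an estimated correlation). Members of the fibrillar matrix list were higher in 18 of 18, with 15 called and 16 adjusted over the list alone (adjusted p = 3.97e-10, adjusted p = 0.294 with an estimated correlation). Cholesterol synthesis genes were lower in 12 of 12, all called (adjusted p = 2.7e-26, adjusted p = 0.185 with an estimated correlation), among them Hmgcs1 (-1.98, adjusted p = 1.14e-04), Insig1 (-2.34, adjusted p = 2.07e-04) and Idi1 (-2.22). The stem cell gene Lgr6 (-2.52, adjusted p = 1.67e-04) and Calb2 (-2.76, adjusted p = 9.09e-04), a calcium-binding protein of neurons, also fell. In this class neuron markers were lower in 9 of 9, all called (median -1.80), and fibroblast markers higher in 8 of 9 (5 called, median 1.02).

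In pericytes genes of inflammation and of other cell types rose after injury, while their own genes did not pass the test. Pdgfrb had a log2 fold change of -0.01, Kcnj8 of -0.08, Cspg4 of -0.35 (adjusted p = 0.406) and Rgs5 of -0.62 (adjusted p = 0.274). Gfap rose by 3.82 ± 0.45 (adjusted p = 0.00325) and the complement gene C3 by 5.77 ± 0.79 (adjusted p = 0.00874) by edgeR's quasi-likelihood test. Apoe rose from 3515 and 3384 CPM in the uninjured pools to 8098, 17581 and 14448 CPM in the vehicle pools (adjusted p = 0.0153). Gpnmb was at least 21.4-fold higher, with 61 UMIs against 0. The adhesion receptor Cd44 was 52.0-fold higher (counting interval 17.4 to 255) against 3 UMIs, and the chemokine gene Ccl21a 201-fold (35.7 to 7992) against 1 UMI. Dlk1, a Notch ligand, fell by 3.96 ± 0.67 (adjusted p = 0.0168) and Calm2, a calmodulin, by 2.77 ± 0.41 (adjusted p = 0.0105). Dlk1 is also among the leading genes of a neuron cluster, and neuron markers were lower in 7 of 7 in the pericyte class (3 called, median -1.69). Without vehicle day 7 the calls of Apoe (1.72), C3 (5.60), Calm2 (-2.50) and Dlk1 (-3.13) were lost. Complement and MHC genes were higher in 9 of 11, with 3 called over all genes and 3 adjusted over the list alone (camera adjusted p = 9.58e-07, adjusted p = 0.292 with an estimated correlation). Cholesterol synthesis genes were higher in 1 of 11, with 1 called lower and 5 adjusted over the list alone (adjusted p = 5.65e-06, adjusted p = 0.233 with an estimated correlation). Reactive astrocyte genes, which pericytes should lack, were higher in 8 of 10 (adjusted p = 2.7e-10, adjusted p = 0.185 with an estimated correlation), astrocyte markers in 8 of 8 (3 called, median 0.68), oligodendrocyte markers in 8 of 8 (2 called, median 0.81) and macrophage markers in 4 of 6 (1 called, median 1.29).

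In the fibroblast class matrix genes, TGF-beta targets and phagocyte genes rose after injury. Whether fibroblasts themselves made the phagocyte genes was not tested. The secreted phosphoprotein Spp1 rose by 3.61 (adjusted p = 9.37e-06 by edgeR's quasi-likelihood test), the matrix protein Postn by 2.88 (adjusted p = 7.16e-04), the collagen crosslinker Loxl2 by 1.46 (adjusted p = 0.00453), the basement membrane collagen Col4a1 by 1.67 (adjusted p = 0.0102), Fn1 by 1.08 (adjusted p = 0.0336) and the transcription factor Runx1 by 3.13 (adjusted p = 0.00161). Col1a1 had 1.15 (adjusted p = 0.0994). The macrophage genes Trem2 (4.47, adjusted p = 4.75e-04), Mpeg1 (4.06, adjusted p = 0.0031) and Ctss (4.33, adjusted p = 0.00821) also rose. Mrc1 (-2.88, adjusted p = 9.64e-04) and Lyve1 (-2.07, adjusted p = 0.00728), scavenger and hyaluronan receptors of border macrophages, fell, as did Sfrp5, an inhibitor of Wnt signalling (-3.14, adjusted p = 0.00398). Without uninjured pool 1 the calls of Ctss (4.63), Col4a1 (1.51), Loxl2 (1.38), Fn1 (0.94) and Lyve1 (-1.51) were lost. Without uninjured pool 2 those of Ctss (4.09), Col4a1 (1.87), Loxl2 (1.59), Fn1 (1.23) and Mpeg1 (3.86) were lost, and Fn1 also lost its call without vehicle day 3 (0.92) or day 7 (1.02). Fibrillar matrix genes were higher in 18 of 19, with 3 called and 9 adjusted over the list alone (camera adjusted p = 3.2e-06, adjusted p = 0.394 with an estimated correlation). TGF-beta targets were higher in 8 of 9, with 4 called and 7 adjusted over the list alone (adjusted p = 3.69e-05, adjusted p = 0.207 with an estimated correlation). The lipid-laden phagocyte genes were higher in 14 of 14, with 10 called (adjusted p = 1.18e-24, adjusted p = 0.185 with an estimated correlation). Oligodendrocyte markers were higher in 8 of 8 in this class (6 called, median 1.11) and neuron markers lower in 9 of 9 (3 called, median -0.87). Of 8 macrophage markers, 4 were called higher and 2 lower.

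Endothelial cells had 67 genes past the threshold. Ccl21a (4.66, adjusted p = 0.00957) and Ccl19 (4.21, adjusted p = 0.0168), chemokines that draw lymphocytes, rose, as did Lbp, which binds bacterial lipopolysaccharide (3.48, adjusted p = 0.00957), the transcription factor Lhx6 (3.81, adjusted p = 0.00957) and Spp1 (3.00, adjusted p = 0.0168). The heat shock gene Hspa1a fell by 2.54 (adjusted p = 0.0167 by edgeR's quasi-likelihood test), and Gpnmb was at least 25.5-fold higher. These calls rested on both uninjured pools, since edgeR called 0 genes in this class without uninjured pool 1 (925 at an unadjusted p under 0.05) and 1 without uninjured pool 2. Without uninjured pool 1 the values of Ccl21a, Ccl19, Lbp, Lhx6, Spp1 and Hspa1a were 3.90, 3.70, 2.89, 3.79, 2.26 and -2.34. Genes of the blood-spinal cord barrier were higher in 1 of 10, with 0 called by edgeR over all genes or over the list alone (camera adjusted p = 0.0059, adjusted p = 0.418 with an estimated correlation). Fibroblast markers were higher in 5 of 5 (1 called, median 1.46) and oligodendrocyte markers in 7 of 8 (median 0.96).

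In the microglia class, which is cluster 22 alone, homeostatic genes fell and genes of lipid-laden phagocytes rose. The class leaves out the unnamed clusters 10 and 32, which also scored highest as microglia. Cluster 10 held 277, 683 and 462 cells in the vehicle pools at days 3, 7 and 14, against 100, 205 and 152 in the class. In uninjured pools 1 and 2 it held 13 and 8 cells, against 104 and 125 in the class. P2ry12 (ENSMUSG00000036353, chromosome 3, 59216272 to 59262871), the ADP receptor of resting microglia, fell by 1.51 (adjusted p = 2.16e-09 by edgeR's quasi-likelihood test), while Apoe rose by 4.05 (adjusted p = 1.33e-15), Spp1 by 3.23 and the lipid exporter Abca1 by 4.28. Homeostatic microglia genes were lower in 9 of 9, all called (camera adjusted p = 4.78e-18, adjusted p = 0.201 with an estimated correlation), and the phagocyte list was higher in 12 of 13, with 10 called (adjusted p = 5.34e-40, adjusted p = 0.185 with an estimated correlation). Oligodendrocyte markers were higher in 6 of 8 in this class (3 called, median 0.52). Macrophages of injured cord, from other clusters than those of uninjured cord, had Spp1 higher by 8.49, Apoe by 2.66 and Gpnmb by at least 445-fold, and Retnla (-6.78) and Lyve1 (-5.20) lower. Cspg4 was 22.5-fold higher in them (counting interval 4.04 to 892) against 1 UMI. In OPCs Cspg4 (-0.80, adjusted p = 0.00597), Pdgfra, a PDGF receptor (-0.63, adjusted p = 0.0224), and Tnc (-1.54) fell. Astrocyte markers were lower in 7 of 8 in this class (4 called lower and 1 higher, median -1.03) and oligodendrocyte markers higher in 6 of 8 (2 called, median 0.62). Cspg4 and Pdgfra lost their calls without uninjured pool 1 (-0.84 and -0.62) or uninjured pool 2 (-0.76 and -0.65), and Pdgfra also without vehicle day 3 (-0.59) or day 7 (-0.60). In oligodendrocytes C4b rose by 3.47, and the complement and MHC genes were higher in 10 of 10, all called (adjusted p = 9.37e-23, adjusted p = 0.201 with an estimated correlation). Neuron markers were lower in 9 of 9 in oligodendrocytes (6 called, median -1.14) and fibroblast markers higher in 6 of 8 (3 called, median 0.68).

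Cholesterol synthesis genes moved down after injury beyond astrocytes. All 12 were called lower in oligodendrocytes (camera adjusted p = 3.21e-24, adjusted p = 0.201 with an estimated correlation), and in OPCs 12 of 12 were lower, with 9 called and 11 adjusted over the list alone (adjusted p = 1.78e-19, adjusted p = 0.185 with an estimated correlation). In microglia 9 of 9 were lower, with 4 called and 6 adjusted over the list alone (adjusted p = 2.03e-05, adjusted p = 0.281 with an estimated correlation). Fry, which tests a list by itself, gave an adjusted p of 0.00946 in astrocytes and 0.0268 in oligodendrocytes. In the class order above, edgeR called 103, 517, 38, 2066, 335, 661, 176 and 1274 genes higher and 73, 467, 29, 2079, 367, 466, 252 and 1390 lower in injured cord. Without uninjured pool 1 it called 139, 113, 0, 1508, 330, 733, 91 and 726 genes in all, and without uninjured pool 2 it called 77, 55, 1, 1857, 302, 750, 205 and 554. Without vehicle day 3 it called 99, 996, 144, 3779, 683, 918, 253 and 2195, without day 7 it called 19, 643, 23, 3088, 404, 897, 142 and 1429, and without day 14 it called 184, 1354, 214, 4950, 717, 1052, 902 and 3767. Treatment with vehicle and injury were given together, so neither can be read alone.

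**Figure D4:**
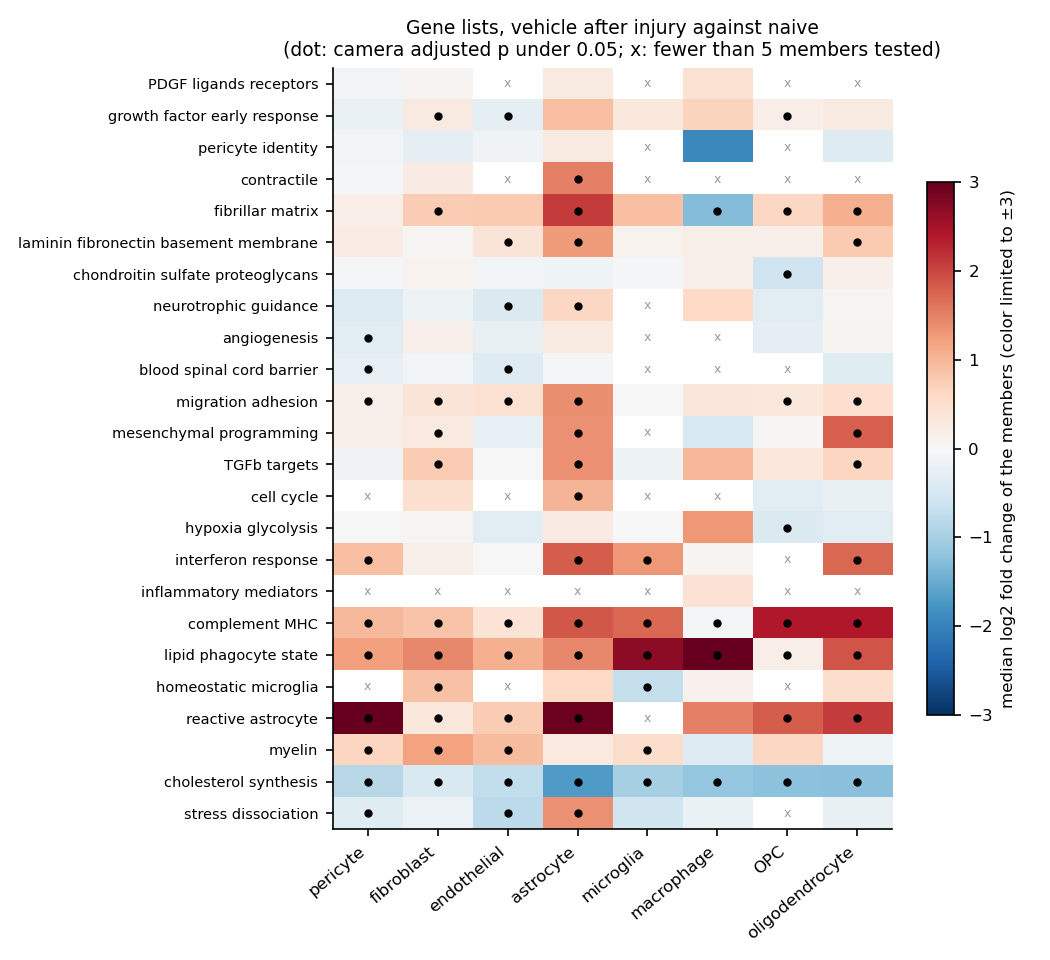
Median log2 fold change (colour) of 24 gene lists in 8 cell classes, vehicle after injury against uninjured cord. Dots mark lists with a camera adjusted p under 0.05 at the preset correlation (75 of 157, and 0 with an estimated correlation), and crosses mark lists with fewer than 5 measured members.

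Time after injury was read from day 14 against day 3 of both treatments, with 1 pool of each treatment at each day. In pericytes 4 genes of the fibrillar matrix fell, and no pericyte identity gene passed the test over all genes. Col1a1 went from 412 to 37.3 CPM in the vehicle pools and from 1504 to 134 CPM in the PDGF-BB pools (log2 fold change -3.46 ± 0.23, adjusted p = 7.93e-06 by edgeR's quasi-likelihood test). The proteoglycan Dcn (-4.19 ± 0.50, adjusted p = 0.00277), the growth factor Igf2 (-2.88 ± 0.22, adjusted p = 3.25e-05), the laminin chain Lama1 (-2.73, adjusted p = 0.00565) and Col1a2 (-2.18, adjusted p = 0.00293) also fell. Lcn2 (2.91, adjusted p = 0.0146), the endothelin receptor Ednrb (2.70, adjusted p = 0.0214) and the interferon-induced Isg15 (1.83, adjusted p = 0.0148) rose. Fibrillar matrix genes were higher in 3 of 14, with 4 called lower and 7 adjusted over the list alone (camera adjusted p = 5.7e-15, adjusted p = 0.539 with an estimated correlation). Pericyte identity genes were higher in 11 of 11, with 0 called by edgeR over all genes and 8 adjusted over the list alone (adjusted p = 8.42e-09, adjusted p = 0.539 with an estimated correlation), with Rgs5 at 0.94 (adjusted p = 0.0791) and Pdgfrb at 0.49 (adjusted p = 0.42). Fibroblast markers were lower in 8 of 8 (5 called, median -2.11) in this class. The calls rested on PDGF-BB day 3, without which edgeR called 0 genes in pericytes (706 at an unadjusted p under 0.05). Without it Col1a1 had -3.29, Dcn -3.41, Igf2 -3.03, Lama1 -2.85, Col1a2 -1.89, Lcn2 2.57, Ednrb 2.87 and Isg15 1.80. Without vehicle day 3, Col1a1 was the gene called.

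Col1a1 also fell with time in fibroblasts and astrocytes. In fibroblasts Col1a1 fell by 1.43 ± 0.28 (adjusted p = 0.0325), Col3a1 by 1.49 (adjusted p = 0.0227), Col4a1 by 1.43 (adjusted p = 0.0125), Gpnmb by 2.93 (adjusted p = 0.00649) and Fcgr2b by 2.74 (adjusted p = 0.0034), by edgeR's quasi-likelihood test. Ccl19 (2.05, adjusted p = 0.0198) and Vtn, a matrix protein of pericytes (1.46, adjusted p = 0.0212), rose. Without PDGF-BB day 3 the calls of Col1a1 (-1.34), Col3a1 (-1.69), Col4a1 (-0.99), Ccl19 (1.24) and Vtn (0.96) were lost, and without vehicle day 3 those of Col1a1 (-1.50) and Col3a1 (-1.29). Fibrillar matrix genes were higher in 4 of 19, with 2 called lower, and adjusted over the list alone 8 lower and 1 higher (camera adjusted p = 8.32e-06, adjusted p = 0.539 with an estimated correlation). Macrophage markers were lower in 6 of 6 in this class (2 called, median -1.91). In astrocytes the fibulin Fbln2 (-2.84, adjusted p = 7.46e-04), Col1a1 (-1.37, adjusted p = 0.00582), Timp1 (-1.63, adjusted p = 0.00173), Fn1 (-2.17, adjusted p = 0.00894) and Spp1 (-1.73, adjusted p = 0.00285) fell. The GABA transporter Slc6a11 (1.63, adjusted p = 0.00764) rose, but not past the threshold without PDGF-BB day 3 (1.36). In this class fibroblast markers were lower in 9 of 10 (3 called, median -0.89) and macrophage markers in 5 of 5 (2 called, median -1.77). Reactive astrocyte genes were lower in 12 of 12, with 3 called and 9 adjusted over the list alone (adjusted p = 1.52e-09, adjusted p = 0.539 with an estimated correlation). In endothelial cells the adhesion molecule Vcam1 rose by 3.57 (adjusted p = 0.0116) and Rgs5, a pericyte gene, by 1.72 (adjusted p = 0.0116), while Col4a1 fell by 1.09 (adjusted p = 0.0226), a call lost without vehicle day 14 (-0.95). Pericyte markers were higher in 5 of 5 in the endothelial class (1 called, median 1.16), astrocyte markers in 7 of 7 (1 called, median 1.17) and oligodendrocyte markers in 8 of 8 (median 0.77).

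Cells of the immune and oligodendrocyte lines changed as well between day 3 and day 14. In macrophages Thbs1, a matricellular protein (-4.74), and the acute-phase gene Saa3 (-4.61) fell and Lyve1 rose (3.03), all by edgeR's quasi-likelihood test. Lyve1 is among the leading genes of cluster 25, which made up 0.60% and 0.88% of cells at days 3 and 14 after vehicle and 0.98% and 1.06% after PDGF-BB. Cluster 19, the other part of the class, made up 6.12% and 3.44% after vehicle and 9.45% and 2.30% after PDGF-BB. The MHC class II genes H2-Aa and Cd74 rose by 2.58 and 2.48, but by 0.48 and 0.50 without PDGF-BB day 14, where neither passed. In OPCs the matricellular gene Ccn3 (-6.08) and Id3, an inhibitor of differentiation (-3.55), fell. Id1 (-3.84) did as well, but not without vehicle day 14 (-3.24) or PDGF-BB day 14 (-4.72). The cell cycle genes Top2a, Troap and Kif18b were among the leading genes of cluster 26, which was named erythroid. At Leiden resolution 2 they were among those of cluster 59 (131 cells), named OPC with 8 of 8 markers raised. Dividing OPCs may therefore lie outside the OPC class tested here. Cell cycle genes were lower in 6 of 6 in OPCs, with 0 called by edgeR over all genes and 4 adjusted over the list alone (camera adjusted p = 2.81e-05, adjusted p = 0.539 with an estimated correlation). Chondroitin sulfate proteoglycan genes were higher in 12 of 13, with 1 called and 4 adjusted over the list alone (adjusted p = 7.09e-05, adjusted p = 0.539 with an estimated correlation), and neuron markers in 8 of 8 (median 1.23). Cholesterol synthesis genes were higher at day 14 in 11 of 12 in astrocytes (adjusted p = 5.61e-06, adjusted p = 0.539 with an estimated correlation) and in 9 of 12 in oligodendrocytes (adjusted p = 0.00108, adjusted p = 0.539 with an estimated correlation). Neuron markers were higher in 7 of 9 in astrocytes (2 called, median 0.55) and in 8 of 8 in oligodendrocytes (4 called, median 0.91).

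In the class order above, 8, 61, 22, 146, 20, 237, 15 and 854 genes were higher and 20, 81, 9, 203, 6, 166, 18 and 683 lower at day 14. Without vehicle day 3 edgeR called 1, 56, 99, 440, 104, 436, 556 and 2010 genes, without vehicle day 14 it called 169, 198, 36, 962, 216, 466, 89 and 403. Without PDGF-BB day 3 it called 0, 22, 353, 169, 25, 188, 66 and 1072, and without PDGF-BB day 14 it called 124, 204, 133, 515, 37, 272, 9 and 81. The day 3 pools had the fewest UMIs, so day and depth went together in this comparison.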

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

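The tests of eGFP, of the pericyte genes except the count of cells that carry Tagln, and of the corticosteroid genes were chosen after the results had been seen, as were the other splits of the pools. In 82 groups of pools, 8 values stood apart from the rest by Dixon's test, which chance does in about 1 in 20 groups. The Y-linked genes together had 0.0819 CPM in vehicle day 7, against 150.3 to 267.9 CPM in the other pools. Among the 6 injured pools, PDGF-BB day 3 had 1498 raw CPM of Col1a1 (others 33.8 to 400.5) and 102 CPM of Tnc (6.62 to 18.3) in the pericyte class, and vehicle day 7 had 10153 CPM of Gfap there (2746 to 5188). Among the same 6 pools, PDGF-BB day 3 had 141 CPM of Lama4 (246.5 to 265.9) and 2598 CPM of Col4a1 (585 to 1207) in fibroblasts, and vehicle day 3 had 303 CPM of Lamc1 in endothelial cells (172 to 199) and 436 CPM of Tnc in astrocytes (183 to 270).

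eGFP was higher in the PDGF-BB pools, with a mean log2 ratio of 1.57 over days 3 and 7 in pericytes and OPCs together. The counts of these pools argue against a more active Cspg4 promoter after PDGF-BB as the cause, since Cspg4 itself had a mean log2 ratio of -0.32 in the same cells. It had -0.71 at day 3 and 0.07 at day 7, with upper counting bounds of -0.38 and 0.24, against 1.33 and 1.80 for eGFP. Pdgfrb had -0.93 and 0.42 in the same sum, whose mix of the 2 classes can differ between pools. The bounds cover counting error in 1 pool per treatment and day, so they cannot speak for other animals. In the vehicle day 14 pool the genes within 100 kb of Cspg4 had a median log2 ratio of -1.50 to the other pools in neurons, and those farther away 0.05. This is consistent with a genomic transgene that carries these neighbours and that was absent from the animals of vehicle day 14, and with animals that differ in copies of it, as a hypothesis. Animals that differ between the pools and PDGF-BB itself stay open for the other days.

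Tagln, Tpm2 and Col1a1 were higher in the pericyte class after PDGF-BB. The fibroblast class of the PDGF-BB pools held at most 0.522 times the pericyte level of Tagln or Tpm2. Caught fibroblasts at that class average could therefore not bring the pericyte class to its level. The ratio of averages cannot speak for single fibroblasts with high levels. In PDGF-BB day 3, 92.2% of the Tagln UMIs and 75% of the Tpm2 UMIs each lay in 1 of 25 cells. For Col1a1 fibroblasts caught in the class stay open, since 6 other fibroblast markers rose by a median of 0.781 of what such cells would bring. A few smooth muscle cells caught in the class stay open for Tagln as well, since at most 3 cells of a PDGF-BB pool held most of its Tagln UMIs. For Tpm2, where 1, 5 and 3 cells held most UMIs at days 3, 7 and 14 after PDGF-BB, such cells were not tested. A response of the pericytes to PDGF-BB, which the design names, is therefore 1 of several explanations that may hold, and it was not tested apart from these.

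The genes induced by corticosteroids were lower after PDGF-BB, with a median of -0.37 over the 8 classes and a lower median in 8 of 8. The uninjured pools of the wells showed no offset of this size and direction in 7 classes (median 0.0438, SE over classes 0.0865, from -0.10 to 0.56). These classes share 1 uninjured pool per well and are not replicates, so an offset of the capture wells cannot be excluded. OPCs were set apart after their value was seen. In them the uninjured pools differed by -0.41 and the treatments by -0.32. With the uninjured pools as an offset, Sgk1 and Plin4 had -1.11 and -1.06 in oligodendrocytes, but -0.60 and -0.23 in cluster 6, where they had been -1.20 and -1.26. The pools without Y-linked transcripts or without eGFP stay open as a cause, since at day 3, which holds neither, the median was -0.099 (SE 0.0932 over classes), which is too close to 0 to decide. Day 3 was not free of such differences either. In its cells with at least 20000 UMIs the median Y-linked UMIs were 0 after vehicle and 6 after PDGF-BB. A different time of day at collection could not be told apart from the treatment either, since the comparison of 11 clock genes (median absolute log2 fold change 0.219) with the corticosteroid genes (0.368) decides nothing when Per1, a clock gene that was called, stands in the second list. An effect of PDGF-BB or of stress in the animals may also underlie the pattern and was not tested.

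With 3 pools against 3 there are 10 splits, too few for a share under 0.05. The real split called 184 genes over the 8 classes and the highest other split 72, so that 1 of the 10 reached the real count. For gene lists the real split called 44 and the highest other 46, and 3 of the 10 reached the real count. With the day term, the 6 splits that keep both pools of a day together make 3 contrasts, each counted 2 times. The one with 72 genes and 46 lists compares the pair of day 7 pools, of which the vehicle pool lacks Y-linked transcripts. Among the 4 splits that part the pools of each day, the real one had 184 genes against at most 30 in the others, and 44 lists against at most 38.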

How the results depend on the processing

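Leaving out a pool of day 3 or 14, and leaving out a day or pool for shares and lists, were chosen after seeing the data, as were the tests of thinned eGFP in neurons, committed oligodendrocytes and clusters 6 and 10. Most named genes were picked for 1 direction in all days or pools, so that few could reverse when 1 was left out. Of 696 values of 70 genes between PDGF-BB and vehicle under other settings, 479 were the same, 199 lost their call, 16 gained one and 2 reversed. Against uninjured cord, 790 of 852 values of 78 genes were the same and 62 lost their call, and between day 14 and day 3, 462 of 540 values of 60 genes were the same, 76 lost their call and 2 gained one. RLE scaling moved no split of higher against lower genes by over 10 percentage points. For macrophages against uninjured cord, at least 1000 UMIs per cell left no fit. The day 3 pools, with the fewest UMIs, limit what can be seen at that day. Pools were paired by day in the comparison of treatments. By replicate number, no paired analysis was possible because the 2 samples share fewer than 2 of them. Except where fewer genes, cells or pools enter by construction, the cause was not tested.

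The values below are genes called, in place of the counts of the report. Without the low-count filter, PDGF-BB against vehicle gave 27 in pericytes, 410 in fibroblasts, 57 in endothelial cells, 52 in astrocytes, 16 in microglia, 99 in macrophages, 18 in OPCs and 213 in oligodendrocytes. Against uninjured cord it gave 680 in pericytes, 1479 in fibroblasts, 37 in endothelial cells and 718 in OPCs. For day 14 against day 3 it gave 149 in pericytes, 542 in fibroblasts, 215 in endothelial cells, 661 in astrocytes, 169 in microglia, 691 in macrophages and 369 in OPCs. With doublets kept, PDGF-BB against vehicle gave 14 in pericytes, 0 in endothelial cells (edgeR, 341 at an unadjusted p under 0.05), 15 in astrocytes, 2 in macrophages and 1 in OPCs, injury gave 285 in endothelial cells, and day 14 gave 16 in pericytes, 1 in endothelial cells, 781 in astrocytes and 3 in OPCs.

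DESeq2 gave 54 genes in fibroblasts, 9 in astrocytes, 0 in microglia, 0 in macrophages, 1 in OPCs and 16 in oligodendrocytes for PDGF-BB against vehicle, with 30 and 133 at an unadjusted p under 0.05 in microglia and macrophages, where edgeR called 1 and 7. It gave 522 in fibroblasts, 212 in microglia, 117 in OPCs and 1677 in oligodendrocytes against uninjured cord. For day 14 against day 3 it gave 11 in pericytes, 62 in fibroblasts, 9 in endothelial cells, 184 in astrocytes, 10 in microglia, 95 in macrophages, 9 in OPCs and 654 in oligodendrocytes. With at least 1000 UMIs per cell, PDGF-BB against vehicle gave 2 in astrocytes and 1 in macrophages, and day 14 gave 12 in endothelial cells and 13 in OPCs. All 8 pools in 1 fit gave 429 in fibroblasts, 164 in endothelial cells, 380 in microglia, 35 in OPCs and 1483 in oligodendrocytes against uninjured cord.

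Without the day term edgeR called 0 genes in each class (332, 921, 278, 484, 216, 338, 240 and 322 at an unadjusted p under 0.05, in the order of the report). With the uninjured pools as an offset it called 20 in pericytes, 12 in endothelial cells, 2 in macrophages, 4 in oligodendrocytes and 0 in fibroblasts, astrocytes, microglia and OPCs (621, 350, 321 and 302 at an unadjusted p under 0.05). Gpnmb in fibroblasts and Best1 in macrophages then reversed, to log2 fold changes of 0.98 and 4.39. Of the lists, camera with an estimated correlation called 0 in each of the 3 comparisons (lowest adjusted p 0.603, 0.131 and 0.539), and fry called 0, 25 and 0 (lowest adjusted p 0.398, 0.00946 and 0.337).

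Shares of cells reversed in their mean log2 ratio of PDGF-BB over vehicle for erythroid cells with at least 1000 UMIs per cell (0.0508), and at Leiden resolution 2 for macrophages (0.16) and microglia (-0.14). The erythroid class is cluster 26, whose leading genes include the cell cycle genes Top2a and Troap. The macrophage and microglia classes hold other cells at resolution 2, so these values do not compare the same cells. Microglia there join clusters of 1079, 1436 and 680 cells, against 1132 in cluster 22. Macrophages join clusters of 818 and 335 cells, against 1435 and 328. With cells thinned to 1000 UMIs an eGFP UMI was seen in 9.88% of OPCs, 5.92% of pericytes, 1.43% of cluster 10, 1.32% of neurons, 1.16% of all cells, 0.846% of cluster 6, 0.839% of macrophages, 0.583% of astrocytes, 0.558% of fibroblasts, 0.511% of oligodendrocytes, 0.466% of committed oligodendrocytes, 0.385% of endothelial cells and 0.091% of microglia. Of 672 levels of the fixed genes per pool in pericytes, fibroblasts, endothelial cells and astrocytes, 387 fell outside their counting interval after this thinning.

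Without each day in turn, PDGF-BB against vehicle gave 6 to 19 genes in pericytes, 43 to 214 in fibroblasts, 2 to 46 in endothelial cells, 9 to 813 in astrocytes, 0 to 39 in microglia, 40 to 97 in macrophages, 0 to 31 in OPCs and 21 to 313 in oligodendrocytes. Without each pool, injury gave 19 to 184 in pericytes, 55 to 1354 in fibroblasts, 0 to 214 in endothelial cells, 1508 to 4950 in astrocytes, 302 to 717 in microglia, 733 to 1052 in macrophages, 91 to 902 in OPCs and 554 to 3767 in oligodendrocytes. Day 14 against day 3 gave 0 to 169 in pericytes, 22 to 204 in fibroblasts, 36 to 353 in endothelial cells, 169 to 962 in astrocytes, 25 to 216 in microglia, 188 to 466 in macrophages, 9 to 556 in OPCs and 81 to 2010 in oligodendrocytes. The lists called ranged from 37 to 60, from 64 to 75 and from 51 to 65. Without each day, the mean log2 ratios of shares ranged from -0.0888 to 0.0119 for astrocytes, -0.669 to 0.0157 for committed oligodendrocytes, -0.60 to 0.22 for erythroid cells, -0.0074 to 0.394 for fibroblasts, -0.33 to 0.17 for macrophages, -0.13 to 0.25 for microglia, -0.0379 to 0.0915 for neurons, -0.21 to 0.19 for oligodendrocytes, -0.30 to 0.19 for pericytes, -0.159 to 0.0324 for cluster 6, -0.495 to 0.0847 for cluster 10 and -0.604 to 0.025 for cluster 19.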

Other observations

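The tests of neurons and of clusters 6 and 10 were chosen after the data had been seen. Neurons, the most numerous class, changed after injury, when vehicle pools were compared with uninjured cord by edgeR's quasi-likelihood test. They had 2299 higher and 2901 lower genes, but edgeR called 86 in all without uninjured pool 1, 25 without uninjured pool 2, 44 without vehicle day 7 and 1530 with all 8 pools in 1 fit. Slc17a7, a vesicular glutamate transporter, fell by 3.81 ± 0.32 on the log2 scale (adjusted p = 0.00257), Calm2 by 1.82 (adjusted p = 0.00962) and the cholesterol synthesis genes Fdft1 by 1.67 (adjusted p = 0.00913) and Hmgcs1 by 1.31 (adjusted p = 0.00436). Cholesterol synthesis genes were lower in 12 of 12, with 11 called (camera adjusted p = 1.35e-19, adjusted p = 0.0628 with an estimated correlation, fry adjusted p = 0.00447). The phagocyte genes Lyz2 (4.34, adjusted p = 0.00241), Mpeg1 (3.71, adjusted p = 0.00206) and C1qb, a complement gene (2.78, adjusted p = 0.00206), rose in the same class. Without uninjured pool 1 the calls of Calm2 (-1.88) and Fdft1 (-1.73) were lost, and without uninjured pool 2 those of Calm2 (-1.78), Fdft1 (-1.62) and Hmgcs1 (-1.21). Without vehicle day 7 those of Calm2 (-1.82), Fdft1 (-1.71) and Hmgcs1 (-1.24) were lost. Neuron markers fell in 7 of 7 (median -0.94). Of 7 fibroblast markers, 4 were called higher and 2 lower (median 0.67). Of 7 astrocyte markers, 1 was called higher and 3 lower (median -0.56). From day 3 to day 14 neuron markers were higher in 7 of 8, with 6 called (median 0.93), and Sprr1a, a gene of injured neurons, fell by 1.77 (adjusted p = 0.00638), while Calm2 rose by 2.09 (adjusted p = 0.00771) and Fdft1 by 1.33.

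After PDGF-BB, 15 genes were higher and 20 lower in cluster 6, which is led by oligodendrocyte genes. In place of these 35 calls, edgeR made 145 without day 3, 9 without day 7, 52 without day 14 and 2 with the uninjured pools as an offset, and DESeq2 made 3. With doublets kept 5 were higher and 17 lower. Cholesterol synthesis genes were higher in 12 of 12, with 6 called, among them Hmgcs1 (0.69, adjusted p = 0.00401), Lss (0.64) and Insig1 (0.52). The list had a camera adjusted p of 1e-25 and an adjusted p of 0.759 with an estimated correlation. Sgk1 fell by 1.20 (adjusted p = 7.87e-05) and Plin4 by 1.26 (adjusted p = 0.00401), and with the offset they had -0.60 and -0.23 and did not pass. Without day 7 the calls of Hmgcs1 (0.45), Lss (0.47) and Insig1 (0.51) were lost. In cluster 10, led by myeloid genes, Ptgds fell by 1.13 (adjusted p = 9.13e-04) and Per1 by 0.68 (adjusted p = 0.00942), a call lost without day 7 (-0.59). By edgeR's quasi-likelihood test Penk also fell there (-1.04, adjusted p = 0.018). Higher in cluster 10 were Acod1 (4.50, adjusted p = 0.0093, mean 10.9 CPM) and mt-Co1 (0.64, adjusted p = 0.018). In neurons edgeR called 0 genes between PDGF-BB and vehicle, with 1164 at an unadjusted p under 0.05 and 16 by DESeq2.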
